A study of Mus musculus with 2 samples.

How the data were processed

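Polyadenylated RNA was measured by sequencing in wild-type E14 cells, a mouse embryonic stem cell line derived from a blastocyst of the 129/Ola background. Per the labels, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, and the description names a reverse-stranded protocol. The labels hold 1 group of 2 libraries. Replicate 1 carries the age label P33 and replicate 2 the age label P42. In cell culture such labels usually give a passage number, which the labels used here do not spell out, so the libraries are called the P33 library and the P42 library.

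The authors deposited whole-number read counts per Ensembl gene, with no normalization, in 1 table per library. Per the submitters' processing notes, STAR 2.4.2a and featureCounts 1.4.5-p1 were used with the mm10 assembly. The annotation release and the settings for strand and for reads with several positions are not given in the sources used here. Counts of genes with near-identical copies, such as the Zscan4 family, ribosomal protein genes and histone genes, are therefore uncertain. The 43629 gene identifiers were matched to GENCODE M21 on GRCm38, the same assembly as mm10. This gave symbols, coordinates, the length of the merged exons and the GC content of the longest transcript. A match was found for 42548 identifiers, and those without a match held 0.155% of the counts in the P33 library and 0.174% in the P42 library.

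The P33 library held 40139219 counts and the P42 library 39657578. Library sizes were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, which gave factors of 1.050 and 0.952. Levels are given in CPM, the usual scaling of counts by library size, and at these sizes 1 CPM stood for 42.2 counts in the P33 library and 37.8 in the P42 library. Scaling by total counts alone would lower every log2 ratio of P42 over P33 by 0.14. CPM values are not scaled by gene length, so levels of different genes are compared only loosely. A gene was called detected at 1 CPM or more in both libraries. Levels are given as the mean ± SD of the 2 libraries. Nothing in the labels says that the libraries came from separate cultures, so the SD may be partly technical. An SD of 2 values can also lie under the counting error, as for Map2 with 498 and 449 counts. A small SD is therefore no measure of precision.

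Each age label is held by 1 library, so the difference between P42 and P33 has no replicate check and no p-value is given. The log2 ratio of TMM-scaled CPM was computed with a prior count of 0.5. Its exact Clopper-Pearson interval at 95% treats every count as independent and covers counting error only. PCR copies are not independent molecules, so the interval may be too narrow even for that. A gene was counted as higher or lower in the P42 library when its mean CPM was at least 1, the libraries differed at least 2-fold and the interval excluded equality. For the 34 of 39 gene lists with at least 4 members at a mean of 1 CPM, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Chromosome medians over genes with a mean of at least 5 CPM were placed in the same way. These percentiles describe the 2 libraries and are not tests of passage.

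The spread between the libraries was estimated as the common biological coefficient of variation in edgeR, with an intercept-only design. The gene lists, the comparisons of the report, the rule for naming genes and most alternatives were fixed before the data were examined, and the closing section names the tests of explanations chosen later. The rule named the 10 genes of highest mean CPM and the 2 most abundant members of each list, with up to 8 detected members for lists of cell identity, other cell types and karyotype. It also named 7 fixed genes, the 12 genes counted higher and the 12 counted lower whose interval bound lay farthest from equality at a mean of 5 CPM or more, and the chromosomes of most extreme percentile. The choice of 12 in each direction left out gene names starting with Gm and a digit or ending in Rik or -ps. Other genes named in the text were chosen after their values were seen, and some genes that the rule takes are not reported here.

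The alternatives were DESeq2 1.42.0 size factors, total counts, other CPM minimums, other fold thresholds, a prior count of 2, the DESeq2 gene-wise dispersion and each library alone. Added after the data were seen were removal of the trend of the log2 ratio on GC content and exon length, by lowess with a span of 0.3 in statsmodels 0.14.6, removal of chromosomes 1, 15 and Y, and both together. To look at strand, genes lying wholly inside the exons of an abundant gene on the opposite strand were compared with that gene. The other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

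The comparison of genes was tested on simulated data, drawn by Poisson from the real means with no spread between libraries beyond counting error. Among 13762 simulated genes it counted 0% of those changed 1.5-fold, 94% of those changed 2.5-fold, all of those changed 4-fold or 8-fold, and 0 of 13562 unchanged genes. With a GC trend added and then removed it counted 96% of the 2.5-fold genes and 1 unchanged gene. In the simulation of lists, on 13755 genes, 7 of 100 unchanged lists of 15 genes lay outside the central 95% and 100 of 100 lists raised by 0.3 lay above it. All of these rates hold for counting error alone and do not carry over to the real libraries, whose spread was larger.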

Results

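Gene expression was profiled in duplicate libraries of wild-type E14 mouse embryonic stem cells, 1 labelled P33 and 1 labelled P42. The P33 library held 40139219 counts over 22887 genes and the P42 library 39657578 counts over 21826 genes. The first question was which genes these cells express, and the second how far the 2 libraries differ.

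Both libraries showed the expression profile of pluripotent stem cells, with the pluripotency factors among well-expressed genes. All 16 members of the core pluripotency list and all 16 of the naive list were detected, with median levels of 296 and 143 CPM. The transcription factor genes at the centre of the network were expressed at 653 ± 212 CPM for Pou5f1, 461 ± 223 CPM for Sox2 and 635 ± 72.9 CPM for Nanog (SD, n = 2). Dppa5a reached 1574 ± 115 CPM, the chromatin cofactor Trim28 1596 ± 326 CPM, the Nodal co-receptor gene Tdgf1 1026 ± 348 CPM, L1td1 905 ± 20.9 CPM and the RNA-binding factor gene Lin28a 326 ± 75.9 CPM (SD, n = 2). Naive markers included Tfcp2l1 at 933 ± 172 CPM, Zfp42 at 677 ± 39.9 CPM, Esrrb at 580 ± 6.17 CPM, Spp1 at 559 ± 31.6 CPM, Klf4 at 327 ± 259 CPM, Tet2 at 238 ± 83.2 CPM, Tbx3 at 204 ± 30.6 CPM and Klf5 at 149 ± 1.86 CPM (SD, n = 2).

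Genes of the formative and primed states were lower, with 9 of 12 list members detected at a median of 11.5 CPM. The DNA methyltransferase genes Dnmt3b, at 246 ± 199 CPM (SD, n = 2), and Dnmt3a, at 144 CPM in P33 and 125 CPM in P42, led this list. Otx2 stood at 27.5 ± 7.09 CPM (SD, n = 2) and Sox4 at 10.5 CPM in P33 and 30.3 CPM in P42. Foxd3, Zic2, Sall2 and Pou3f1 lay between 11.5 and 3.24 CPM. Among germ cell genes 14 of 17 were detected, led by Mael at 47.6 ± 3.63 CPM and the piRNA pathway gene Piwil2 at 41.6 ± 10.7 CPM, with Ddx4 at 30.5 ± 10.5 CPM and Dazl at 19.7 ± 1.37 CPM (SD, n = 2). The meiotic gene Sycp3 was at 24.8 CPM in P33 and 45.3 CPM in P42. No member of the 2-cell-like list, which marks a rare totipotent-like state of stem cell cultures, was detected in both libraries, and 2 reached 1 CPM in the P33 library. Its most abundant genes, Zscan4d and Zscan4c, had 55 and 56 counts in the P33 library and 3 and 2 in the P42 library.

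Markers of other lineages were mostly low. Primitive endoderm stood higher, with 13 of 18 markers detected, led by the extracellular matrix genes Sparc at 252 ± 51.4 CPM, Lamb1 at 165 ± 0.393 CPM and Lama1 at 147 ± 26.0 CPM (SD, n = 2). Of trophectoderm markers 4 of 14 were detected, Tfap2c at 37.7 ± 2.59 CPM, Krt18 at 10.9 ± 4.34 CPM, Krt8 at 8.92 ± 6.28 CPM and Eomes at 4.88 ± 2.27 CPM (SD, n = 2). Of 12 mesendoderm markers Eomes alone was detected in both libraries, and Mixl1, at 0.849 ± 0.597 CPM, reached 1 CPM in the P42 library. Neuroectoderm had 6 of 15 markers detected, with Tubb3 at 31.4 ± 3.55 CPM, Nes at 15.5 ± 2.46 CPM, Sox11 at 13.4 ± 0.308 CPM, Map2 at 11.9 ± 0.0533 CPM, Neurod1 at 7.75 ± 8.16 CPM and Sox1 at 1.38 ± 0.372 CPM (SD, n = 2). Fibroblast markers reached 1 CPM in both libraries for 5 of 17 genes and in the P33 library for 9, highest for Thy1 at 27.3 ± 3.64 CPM and Col5a1 at 9.29 ± 3.67 CPM, with Pdgfrb, Fbn1 and Loxl1 between 6.03 and 1.62 CPM. Blood and liver markers were detected for 3 of 12 genes, Cd68 at 10.7 ± 4.78 CPM, Cd3e at 2.25 ± 0.817 CPM and Itgam at 1.86 ± 0.493 CPM (SD, n = 2).

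**Figure D1:**
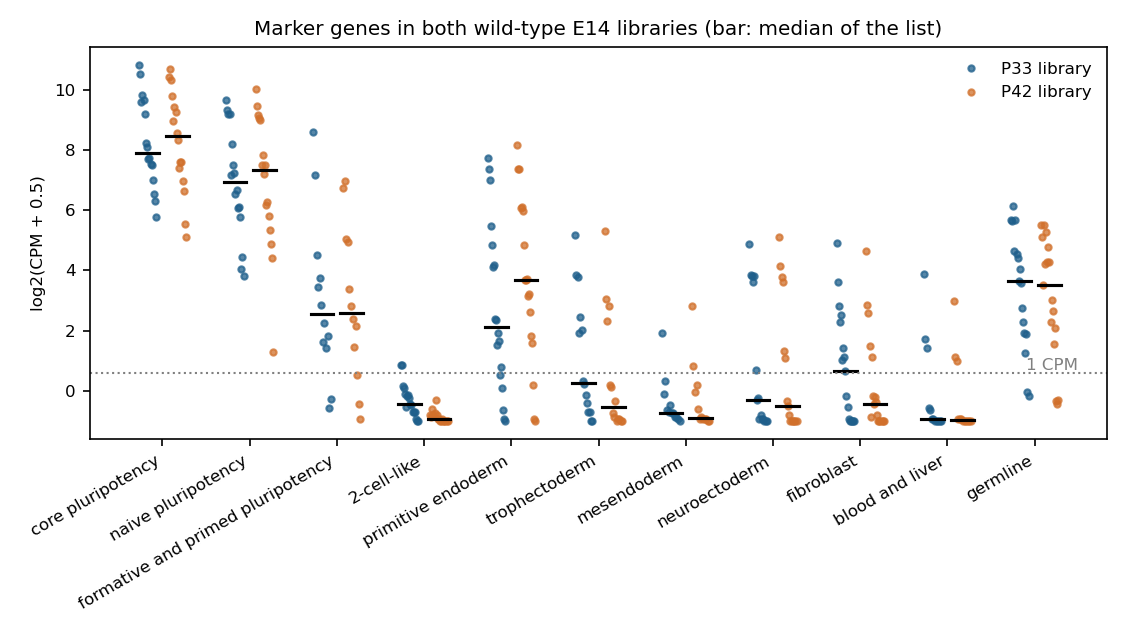
Expression of each marker gene as log2(CPM + 0.5), by list, in the P33 library (blue) and the P42 library (orange); bars are list medians and the dotted line marks 1 CPM. Core and naive pluripotency genes stand highest, with median levels of 296 and 143 CPM, while the medians of the trophectoderm, mesendoderm, neuroectoderm, fibroblast, and blood and liver lists lie near or under 1 CPM.

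In all, 13017 genes were detected in both libraries, 11641 of them protein-coding, with 824 genes at 1 CPM or more in the P33 library alone and 382 in the P42 library alone. The most abundant transcripts came from mt-Co1 at 13379 ± 604 CPM, the elongation factor gene Eef1a1 at 8981 ± 590 CPM, the chaperone gene Hsp90ab1 at 6691 ± 405 CPM and the nucleolar protein gene Ncl at 6217 ± 2877 CPM (SD, n = 2). They were followed by mt-Nd1, mt-Cytb, Pabpc1, Hsp90aa1, Npm1 and Rpl4, with means from 5281 to 3019 CPM. The 10 most abundant genes of each library took 5.91% of the counts in P33 and 5.95% in P42. Genes of the mitochondrial chromosome took 3.48% (3.475 to 3.486, exact 95% binomial interval) in P33 and 2.93% (2.921 to 2.931) in P42. Ribosomal protein genes took 2.22% and 2.14%. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, took 0.00167% and 0.000724%, led by Hist1h2bc at 2.95 ± 1.81 CPM (SD, n = 2) and Hist1h1c at 3.06 CPM in P33 and 1.09 CPM in P42.

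The duplicates were not interchangeable. Across genes, which are not independent replicates, log2 expression correlated with a Pearson r of 0.957 and a Spearman rho of 0.960 over 13737 genes with a mean of at least 1 CPM. The counts differed far beyond sampling noise, with a chi-square of 149 per degree of freedom over 16503 degrees of freedom, so the files are separate libraries. The common biological coefficient of variation was 0.342 over 15535 genes, and 0.188 as the median gene-wise value of DESeq2. The log2 ratio of P42 over P33 had a Spearman rho of −0.39 with the GC content of the longest transcript across genes. Its median ran from 0.33 in the tenth of genes with the lowest GC content to −0.48 in the tenth with the highest.

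At the level of single genes, the P42 library differed from the P33 library at least 2-fold for 2007 genes, 697 higher and 1310 lower. Stra8, the gene for a factor needed to enter meiosis, stood at 9.54 CPM in P33 and 124.7 CPM in P42, a log2 ratio of 3.71 (3.56 to 3.86, 95% counting interval). Dmrt1, a testis transcription factor gene, was higher in P42 by 2.89 (2.76 to 3.03). On the other side Usp26, an X-linked gene of male germ cells, had a log2 ratio of −4.15 (−4.37 to −3.94), and Rhox5, an X-linked homeobox gene of the reproductive tract, one of −3.85 (−3.95 to −3.74). Klhl13, an X-linked ubiquitin ligase adaptor gene, was at 496 CPM in P33 and 32.5 CPM in P42, with a ratio of −3.93 (−4.01 to −3.85).

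The other genes of this selection that were higher in P42 had log2 ratios of up to 3.86, reached by Cyp2b23. They were Msc and Trpa1, neighbours on chromosome 1 at 14753346–14755992 and 14872648–14918862 (mm10), with Vash2 on the same chromosome, Cyp2b23, Tgfbi, the histidine-degrading enzyme gene Hal, Miip, Mobp, Rnf227 and Igf2bp3. Igf2bp3, which encodes an RNA-binding protein, was the most abundant of them, at 40.2 CPM in P33 and 212 CPM in P42. The others that were lower in P42 had ratios from −4.24 to −3.65 and were Dglucy, Plekhg1, the Wnt ligand gene Wnt7b on chromosome 15, Rgs9, the p53 family gene Trp73, Tmem40, Fgfbp1, Rcsd1 and Arhgap45. Plekhg1 stood at 137 CPM in P33 and 8.82 CPM in P42. Rcsd1 lies on chromosome 1, as Msc, Trpa1 and Vash2 do, but went the other way.

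Pluripotency genes differed in direction. Sox2 stood at 303 CPM in P33 and 619 CPM in P42, a log2 ratio of 1.03 (1.00 to 1.06), and Klf4 at 143 and 510 CPM, a ratio of 1.83 (1.79 to 1.87). Pou5f1 was at 803 and 503 CPM, a ratio of −0.67 (−0.70 to −0.65) that did not reach 2-fold, Nanog at 583 and 686 CPM, and Zfp42 at 649 and 705 CPM. Median ratios were 0.08 for the core list and −0.02 for the naive list, both inside the central 95% of random lists. Hprt, a purine salvage gene that is deleted in some E14 sublines, had 66 counts in P33 and 69 in P42. The X-inactivation RNA Xist had 55 counts and 5 counts, while its antagonist Tsix was at 6.61 ± 0.956 CPM, Ftx at 8.58 ± 2.47 CPM and the X-linked regulator Rlim at 271 ± 11.4 CPM (SD, n = 2).

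These counts have no replicate check and depend on scaling. With total counts in place of TMM, 466 genes were higher and 1658 lower, so the share of lower genes was 78.1% in place of 65.3%. With the GC and length trend removed, 668 genes were higher and 997 lower, a share of 59.9%. The share was 57.4% at a minimum of 10 CPM, 54.1% at 1.5-fold and 78.1% at 3-fold.

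Of the 34 gene lists with enough members, 13 had a median outside the central 95% of random lists, 5 of them higher in P42 and 8 lower. Lists of genes that vary independently would give 1.70. Members of a real list can vary together and some lists share genes, so 1.70 is not a chance rate for these lists. Primitive endoderm genes were highest, with a median log2 ratio of 1.37 above those of all 10000 random lists and all 15 members above 0 (Lamb1, at 0.00, lies below 0 when scaled by total counts). Of the 15 members 13 were detected in both libraries. The others passed the minimum only through P42, which by itself placed them above 0. In this list 10 members were counted higher. Among them were the lineage transcription factor genes Gata4 at 1.42, Gata6 at 1.37, Sox7 at 1.70 and Sox17 at 2.11. The endocytic adaptor and receptor genes Dab2 at 1.91 and Cubn at 1.28 and the growth factor receptor gene Pdgfra at 1.37 were others. The abundant matrix genes had ratios of 0.42 for Sparc, 0.36 for Lama1, 0.60 for Col4a1 and 0.68 for Col4a2, the last 2 of which reached 1.15 and 1.36 with the GC and length trend removed. The levels of the transcription factors were low, at 12.3 CPM for Gata4 and 8.42 CPM for Gata6 in P42. Dab2 lies on chromosome 15, where most genes were lower in P42, as described below.

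Cholesterol synthesis genes were also higher in P42, with a median of 0.84 (percentile 100) and 19 of 22 members above 0, some of which, such as Pmvk at 0.12, lie below 0 when scaled by total counts. In this list 7 members were counted higher, with Insig1 at 1.69, Msmo1 at 1.48, Hsd17b7 at 1.44 and Idi1 at 1.32. Hmgcs1, the most abundant member, had a ratio of 0.71. Stress genes of the integrated stress and unfolded protein responses had a median of 0.44 (percentile 99.4), with Atf3 at 2.25 and the cystine transporter gene Slc7a11 at 1.78 among 4 counted higher, Atf5 at −1.14 as the member counted lower, and the chaperone gene Hsp90b1 at 0.61 and the serine synthesis gene Psat1 at 0.55. The G1/S list of replication genes had a median of 0.48 (percentile 98.5), with Mcm6 at 1.06 and Ccne2 at 1.12 counted higher and Mcm3 at 0.63. Both Mcm6 and Mcm3 lie on chromosome 1. Nuclear genes of oxidative phosphorylation had a median of 0.42 (percentile 98.0), with no member counted, and of 0.13 (percentile 44.8) with the GC and length trend removed. Their most abundant members, Atp5b and Atp5a1, had ratios of 0.19 and 0.07.

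Targets of p53, the tumour suppressor induced by DNA damage, were lower in P42, with a median of −0.74 (percentile 0) and 17 of 19 members below 0. Trp53inp1 at −1.26, Plk2 at −1.58 and the cell death gene Bbc3 at −1.60 were among 6 counted lower, Ccng1 had a ratio of −0.74 and the cell cycle inhibitor gene Cdkn1a one of −0.28, while Sesn1 was counted higher at 1.32. DNA methylation genes had a median of −0.56 (percentile 0.03), and 6 of 14 were counted lower. These were Dppa3 at −2.80, the methyltransferase genes Dnmt3l at −2.13 and Dnmt3b at −1.88, the demethylase genes Tet1 at −1.04 and Tet3 at −1.22, and Mbd3 at −1.07. Dnmt1 had a ratio of −0.38, Dnmt3a one of −0.21 and Zfp57, which protects imprints, one of −0.14.

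Imprinted genes, expressed from the maternal or the paternal copy alone, had a median of −0.41 (percentile 0.16), with 8 of 23 counted lower and Grb10 counted higher at 1.01. The growth factor gene Igf2 was at −2.92, Sfmbt2 at −2.27, Peg10 at −1.34 and H19 at −1.09, and Slc38a4 had a ratio of −0.30. Interferon response genes had a median of −1.76 (percentile 0.01), and 4 of 5 testable members were counted lower, Ifitm3 at −2.50, Oas1a at −2.10, Ddx58 at −1.76 and Bst2 at −1.04. With no CPM minimum the interferon median was −0.66 (percentile 3.54), inside the central 95%. Trophectoderm genes had a median of −1.20 (percentile 0.25), with Ascl2 at −2.96, Krt7 at −2.60 and Krt8 at −1.57 counted lower and Eomes at 0.98. Ascl2 and Krt7 lay under 1 CPM in P42 and passed the minimum only through P33, so this median leans on them. The 4 members detected in both libraries ran both ways, with Tfap2c at 0.14 and Krt18 at −0.84 beside Krt8 and Eomes. The keratin genes Krt7, Krt8 and Krt18 lie on chromosome 15, and without chromosomes 1, 15 and Y too few members were left to test. The H3K9 methylation list had a median of −0.18 (percentile 0.95), with the heterochromatin protein gene Cbx5, on chromosome 15, at −1.28 and Ehmt2 at −1.40 counted lower and Suv39h1 at 1.09 counted higher. Glycolysis genes had a median of −0.10 (percentile 1.59), with Pkm at −0.51, Ldha at 0.27 and Pgk1 counted higher at 1.04, and with the trend removed a median of 0.11 (percentile 33.3).

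**Figure D2:**
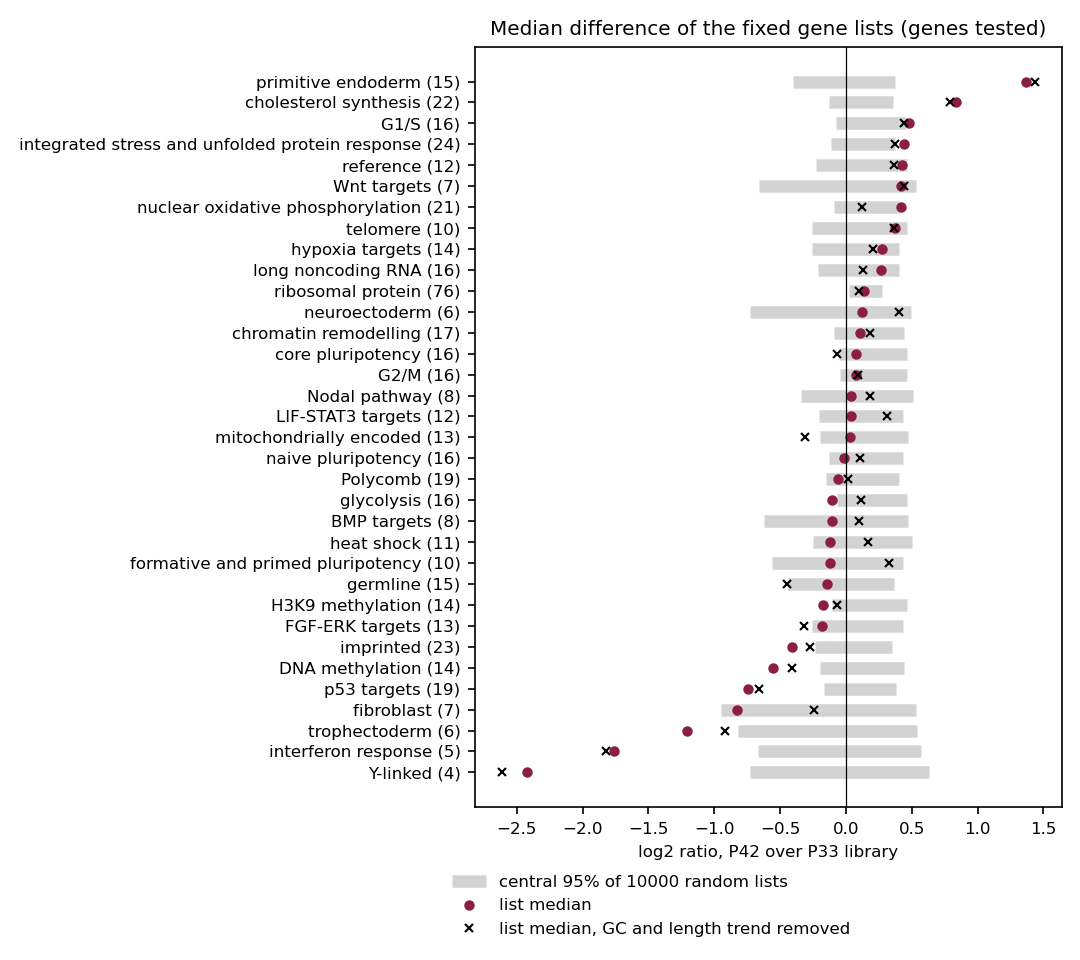
Median log2 ratio of P42 over P33 for the 34 lists with at least 4 members at a mean of 1 CPM (red), the same with the GC and length trend removed (crosses), and the central 95% of 10000 random lists of the same size and expression (grey). Primitive endoderm at 1.37 and cholesterol synthesis at 0.84 lie above their grey bars, and p53 targets at −0.74 and interferon response at −1.76 below.

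The medians of the other lists lay inside the central 95%. For reference genes the median was 0.43 (percentile 96.2), with 9 of 12 members above 0 and 3 counted higher. The 2 most abundant reference genes, Eef2 at −0.45 and Actb at −0.40, went the other way. Further medians were 0.42 for Wnt targets, with Ccnd1 at −0.12 and Tcf7 at 0.42, and 0.37 for telomere genes, with Rif1 at −0.59 and Dkc1 at 0.80. Hypoxia targets had one of 0.27, with Pdk1 at 1.12 and Slc2a1 at 0.11. Long noncoding RNA genes had a median of 0.26, with Malat1 at 0.40 and Lncenc1 at −0.20, ribosomal protein genes one of 0.13, with Rpl4 at 0.10 and Rpl7 on chromosome 1 at 0.95, and chromatin remodelling genes one of 0.11, with Chd4 at −0.07 and Smarcc1 at 0.45. Neuroectoderm genes had a median of 0.12 and G2/M genes one of 0.08, with Top2a at 0.52. The Nodal pathway and LIF-STAT3 target lists had medians of 0.04, and the mitochondrially encoded list one of 0.03. In the Nodal pathway list the antagonist genes Lefty2 and Lefty1, both on chromosome 1, were at 1.92 and 1.25 while Nodal was at −1.51, and Skil had a ratio of 0.06. Medians below 0 were −0.06 for Polycomb genes, with Mtf2 at 0.20 and Jarid2 at 0.22, −0.11 for BMP targets, with Dusp9 at −0.23 and Smad7 at 0.02, and −0.12 for heat shock genes, with Hspd1 at 0.87. They were −0.12 for formative and primed genes, −0.14 for germ cell genes, −0.18 for FGF-ERK targets, with Etv5 at −0.40 and Spry4 at 0.52, and −0.83 for fibroblast markers. In the sum over the 2-cell-like list 270 counts in P33 stood against 36 in P42, a log2 ratio of −2.73 (−3.29 to −2.24).

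Random lists were matched on expression and not on GC content, with which the log2 ratio varied. With the GC and length trend removed, core pluripotency at −0.07, germ cell genes at −0.45, FGF-ERK targets at −0.32 and mitochondrially encoded genes at −0.31 lay below the central 95% and the H3K9 list at −0.07 inside it, while without chromosomes 1, 15 and Y the G1/S list at 0.37 lay inside and the reference list at 0.63 above it. With both steps the germ cell and FGF-ERK lists lay inside again at −0.26 and −0.09 and the naive list below at −0.12. The neuroectoderm list at 0.58, the reference list at 0.54 and the G1/S list at 0.37 then lay above. With the trend removed no G1/S gene was counted, 3 DNA methylation genes (Tet1, Tet3 and Mbd3 not among them) and 5 imprinted genes (H19 not among them) were still counted lower, and Sox2, Bbc3, Atf5, Bst2, Ehmt2 and Pgk1 no longer reached 2-fold. Several of these lay just under 2-fold, with Mcm6 at 0.93, Tet1 at −0.96 and Sox2 at 0.93, and the G1/S median was 0.44 (percentile 99.7).

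By chromosome, genes of chromosome 1 were higher in P42 and genes of chromosomes 15 and Y lower. The 638 genes of chromosome 1 with a mean of at least 5 CPM had a median log2 ratio of 0.66 (percentile 100), and 85.1% of them lay above 0. The 428 genes of chromosome 15 had a median of −0.57 (percentile 0), and 15.7% lay above 0. The Y-linked genes Ddx3y at −3.14 (−3.29 to −2.99), Uty at −1.71 (−1.88 to −1.54), Eif2s3y at −1.55 (−1.68 to −1.43) and Zfy1 at −3.34 (−4.25 to −2.62) were all counted lower, and the list had a median of −2.42 (percentile 0). In the P42 library Ddx3y was at 10.9 CPM, Uty at 9.64 CPM and Zfy1 at 0.397 CPM.

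Chromosome 1 held 26.8% of the genes counted higher and 6.17% of the genes with a mean of at least 1 CPM. Chromosome 15 held 12.6% of the genes counted lower and 3.92% of those genes. Among the abundant genes, Ncl on chromosome 1 had a ratio of 0.98 and Pabpc1 on chromosome 15 one of −0.44. With the GC and length trend removed, the medians were 0.65 for chromosome 1 and −0.47 for chromosome 15, and 1.47-fold and 0.681-fold relative to genes off chromosomes 1, 15 and Y. Chromosomes 3, 7, 13, 14, 17, 18 and X also lay outside the central 95%, with medians between −0.09 and 0.24. With the trend removed chromosomes 13, 18 and X lay inside and chromosomes 6 and 11 outside.

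**Figure D3:**
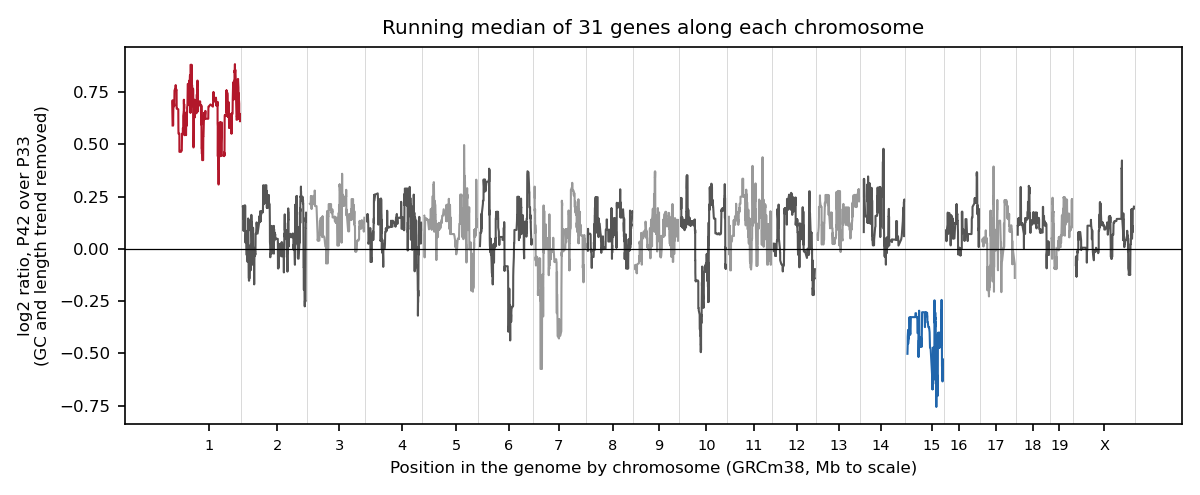
Running median of the log2 ratio of P42 over P33 over 31 neighbouring genes, with the GC and length trend removed, along chromosomes 1 to 19 and X (GRCm38, position to scale). Chromosome 1 (red, median 0.65) and chromosome 15 (blue, median −0.47) lie above and below 0 along their whole length, while the other chromosomes drawn run close to 0 apart from local stretches such as those on chromosomes 6, 7 and 10.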

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

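Removal of the GC and length trend, of chromosomes 1, 15 and Y, and of both together were chosen after the data were seen. No paired analysis was possible because there is 1 group. Detected genes numbered between 13399 and 13841 with 1 library left out, and detected list members between 504 and 512, against 498 in both. With 1 count in both libraries as the minimum 20584 genes were detected. The spread was 0.188 with the DESeq2 gene-wise dispersion. Genes at least 2-fold apart numbered 755 (322 higher, 433 lower) at a minimum of 10 CPM, 3428 (1080 and 2348) with no minimum, 4807 (2207 and 2600) at 1.5-fold and 672 (147 and 525) at 3-fold, as these rules by construction take in fewer or more genes. Without the trend and without chromosomes 1, 15 and Y 840 genes were lower. Without mitochondrially encoded genes the top 10 and top 100 genes took 4.40% and 15.5% in P33 and 4.52% and 16.3% in P42. Of the 13 lists outside the central 95%, 13 stayed there with DESeq2 size factors, total counts or a prior count of 2, 10 at a minimum of 10 CPM and 12 with no minimum. With no minimum interferon response was lost, and the 2-cell-like and fibroblast lists came to lie outside. With the trend removed 10 stayed, without chromosomes 1, 15 and Y 9, and with both 8. Trophectoderm and Y-linked genes had too few members to test at a minimum of 10 CPM and without these chromosomes. In both of these settings nuclear oxidative phosphorylation lay inside the central 95% and the reference list outside it. The nuclear oxidative phosphorylation median lay on the other side of its random median, at 0.13 with the trend removed and at 0.125 with both, and the cause was not tested. At a minimum of 10 CPM chromosome Y had too few genes for a median. Depth limits genes near 1 CPM, which rest on about 40 counts.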

Other observations

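The tests of GC content as the whole cause and of fibrillar collagens were chosen only after the results they bear on were seen, as was removal of the GC and length trend as a setting. The tests on chromosomes 1 and 15 were chosen after their uncorrected medians were seen and before the corrected values and the values by position were computed.

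Among developmental genes not described above, the early neural gene Neurod1 was at 13.5 CPM in the P33 library and 1.99 CPM in the P42 library, a log2 ratio of −2.76 (−3.14 to −2.42). In the germ cell list Tuba3a at −2.68, Rpl10l at −1.52, Hormad1 at −1.36 and Tex101 at −3.39 were counted lower, and the X-linked gene Tex11 was counted higher at 1.17 but stood at 0.86 with the GC and length trend removed. The Nodal-processing protease gene Pcsk6 was at −1.34. The Y-linked genes did not move by 1 common factor, since Ddx3y in P42 stood at 0.114 of its P33 level and Eif2s3y at 0.341. Tagln, a contractile gene of smooth muscle and fibroblasts, was at −2.40 (−3.34 to −1.65). All of these genes were picked after their values were seen or by the naming rule, and none has a replicate check.

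The first pattern is the set of 2007 genes at least 2-fold apart. Pairs of libraries drawn by Poisson from shared means gave a median of 0.0747% of that number, but the counting rule itself fixes this value near 0, so it decides nothing. With the GC and length trend removed 69.6% of the genes, 1396 in number, still passed in the same direction. That share lay between the bounds set in advance for and against GC content or gene length as a cause, so it cannot tell. The later test of GC content as the whole cause set the 1396 genes against the Poisson draws near 0, so it could hardly fail. The fitted trend alone does not account for these 1396 genes, but a part played by GC content or gene length stays open. Fibroblast markers had a median of −0.83, between the sizes set in advance for and against other cells, and of −0.24 with the trend removed. Of 7 tested markers 6 lay below 0 and 2 were counted lower. The 5 detected in both libraries had ratios of −0.27 for Thy1, −0.83 for Col5a1, −0.22 for Pdgfrb, −0.89 for Fbn1 and 0.14 for Loxl1. The others lay under 1 CPM in P42 and passed the minimum only through P33, so the median of −0.83 leans on them. A share of other cells therefore cannot be told apart from other causes by that list. The fibrillar collagens Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, summed to 1.47 CPM in P33 and lay 0.835 CPM lower in P42. That is under the median difference of 5.11 CPM of the genes counted lower, which argues against feeder fibroblasts as their source. Of the other fibroblast markers, Thy1 fell from 29.8 CPM in P33 to 24.7 CPM in P42 and Col5a1 from 11.9 to 6.70 CPM. With the GC and length trend removed, the log2 ratio of Thy1 was −0.007 and that of Col5a1 −0.24. The collagens alone therefore do not settle the question.

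The second pattern is the shift of chromosomes 1 and 15. Removal of the GC and length trend left medians of at least 0.467 in size, and when the genes of each chromosome were split by position into 4 parts of near-equal number, the smallest median of any part was 0.374 in the direction of its chromosome, which argues against GC content and against a single segment or a few genes. A candidate explanation is a difference in copy number of whole chromosomes in part or all of the cells, for which the parts of 1 chromosome should lie close together. Their medians were 0.67, 0.64, 0.63 and 0.65 on chromosome 1 and −0.37, −0.55, −0.50 and −0.43 on chromosome 15, at most 0.180 apart. Relative to genes off chromosomes 1, 15 and Y they were 0.58, 0.55, 0.55 and 0.56 on chromosome 1. On chromosome 15 they were −0.46, −0.64, −0.58 and −0.52. A difference of 3 copies against 2 would give a log2 ratio of 0.58 in size. This remains a hypothesis from RNA of 1 library per label, and DNA was not analysed here.

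The third pattern is the low count of genes inside the exons of an abundant gene on the opposite strand. Over 17 such pairs with a host at 100 CPM or more, the median ratio of counts per kb of the inner gene to its host was 0.000783 and the highest 0.0139. Over 62 pairs with a host at 20 CPM or more, 59 had a ratio below 0.1 and the highest was 79.3. The low ratios of the first set argue against libraries without strand information that were counted on 1 strand. Of the inner genes 35.3% (14.2 to 61.7, exact 95% binomial interval) had no counts, and 54.8% (41.7 to 67.5) in the larger set. Both shares lay under the 90% set in advance for reads counted without regard to strand and dropped as ambiguous. The bound set in advance against this was 50%. The first set lay under 50% with an interval reaching above it, and the larger set lay above 50%. Inner genes held a median of 2 counts in the first set and 0 in the larger, so these shares rest on few reads. The annotation of the authors may also differ from the one used here, so the shares do not decide whether reads were counted without regard to strand. Passage, culture and library preparation are confounded with 1 library per age label, and none of them was tested as a cause.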
